A study of Mus musculus with 2 samples.

How the data were processed

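Immune cells from subcutaneous squamous cell carcinomas of FVB mice were profiled by droplet single-cell RNA sequencing with the 10x Genomics 3' v3 chemistry, per the labels' protocols. Each tumour was a mosaic grown from a mixed injection of the carcinoma lines CIT6, which carries YFP, and CIT9, which carries RFP. Sections were labelled with light-printed oligonucleotide codes (ZipSeq), digested with collagenases I and IV, and sorted for CD45, a surface protein of leukocytes. Both samples belong to 1 group, the untreated mosaic tumour, and are named replicate 1 and replicate 3 as in the labels. The labels do not say whether the tumours came from separate animals, but sex-linked transcripts of their leukocytes differ as in animals of different sex. The tests take the tumour as a block. With 2 samples, p-values measure only how far differences between classes vary between these tumours, over all classes in the fit.

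The deposited matrices hold counts of unique molecular identifiers (UMIs) per feature and barcode, whole numbers that the authors had not normalised. Per the submitters' processing notes the counts came from Cell Ranger 4.0 and the mm10 build, and the file headers name Cell Ranger 4. The annotation release, the handling of multi-mapping reads and any cell filter are not given in the sources used here. Each matrix lists 6794880 barcodes, 31055 genes (YFP and RFP among them) and 3 spatial code features. Replicate 1 held 89040909 gene UMIs and 6525522 code UMIs. Replicate 3 held 170328781 gene UMIs and 4115178 code UMIs. The matrices were not restricted to cells, since 1086240 and 1764026 barcodes had at least 1 UMI, so cells were called here.

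The cell filter, clustering settings, marker lists, gene lists, tests, alternatives and the rule for named genes were chosen before the data were examined, except where stated. A barcode was called a cell if its gene UMI total reached the 99th percentile of the 3000 largest totals divided by 10 (and at least 500), with at least 300 genes and at most 10% mitochondrial UMIs. This UMI minimum came to 5701 in replicate 1 and 9218 in replicate 3, so shallow cells were lost at different depths in each tumour. Doublet scores were computed with scrublet, run through scanpy, within each tumour. Scrublet's own threshold marked 0 and 1 barcodes and was taken as not having worked, so the highest-scoring 0.8% per 1000 cells were removed (116 and 250 barcodes).

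Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes within tumours were taken after setting aside the fixed gene lists, mitochondrial and ribosomal protein genes, Xist, YFP and RFP. Values were scaled within each tumour, reduced to 30 principal components, linked by 15 neighbours and clustered with the Leiden algorithm at resolution 1. T and NK cells, and mononuclear phagocytes with dendritic cells (DCs), were then clustered again in the same way. A cluster was called X-like from 23 fixed marker lists. Each marker's log2(CPM + 10) was scaled from the lowest to the highest cluster, over a span of at least 3, and averaged over a class's markers (CPM: UMIs scaled to a common total per cluster or class). A name needed at least 3 markers detected in 10% of cells and a score of at least 0.5, and no other class could have more markers among the 10 leading genes. Clusters in which another compartment also scored 0.6 or more, and clusters with low UMI counts and no leading marker of their own, stayed unnamed. This scoring rule was set after the data were seen. Class names were rebuilt here and are not the authors' annotation. Versions were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

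For each comparison of classes, UMIs were summed per tumour and class. All named classes with at least 20 cells in each tumour entered 1 fit with the tumour as a block, and the contrast was taken between the classes named. Conventional DC-like sums joined the cDC1-like and cDC2-like classes, mononuclear phagocyte-like sums the monocyte-like and macrophage-like classes, and T-like sums every T cell class. The test was the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM normalisation and filterByExpr, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested at a threshold of 0.05. Genes that had been used for clustering, the markers and both reporters were not tested, because clusters differ in them by construction. Tested genes can vary together with these, so they are not free of that effect. Errors of log2 fold changes are standard errors derived from the F statistic. The tumour block rests on the shared tissue: both classes of a comparison were taken from the same tumours. Over 15 pairs of classes, the differences between tumours had a correlation across genes of 0.0717 to 0.496. On data simulated from the fitted means with 200 genes changed, the test for macrophage-like against monocyte-like sums (8006 genes) recovered 52.6% of genes changed by a fold of 2 and 99.0% of those changed by a fold of 4, and 5.73% of its calls were false. For CD8 T-like against regulatory T-like sums (8009 genes) the values were 20.2%, 72.7% and 1.08%. For NK-like against CD8 T-like sums (8011 genes) they were 27%, 77.8% and 4.59%, and for T-like against mononuclear phagocyte-like sums (8092 genes) 51%, 87.9% and 2.82%. The simulation used the fitted trend of the spread and fixed classes. These rates therefore leave out spread particular to single genes and any error of clustering and naming.

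The 18 gene lists (274 genes) covered T-cell-attracting chemokines, myeloid-attracting chemokines, chemokine receptors, checkpoint ligands and costimulation, checkpoint receptors and exhaustion, cytotoxicity and T helper 1, T helper 2 and 17, naive and memory T cells, interferon-stimulated genes, MHC class II presentation, MHC class I presentation, alternative activation and tissue repair, inflammatory cytokines, hypoxia and glycolysis, lipid handling and lysosome, Fc and pattern-recognition receptors, dissociation stress, and cell cycle. Named genes were, per comparison, up to 3 members of each list and direction with the largest absolute log2 fold change past the threshold and the same direction in both tumours. To these were added, of all genes tested, the 5 largest changes in each direction at 50 CPM or more in the higher class. Cxcl9, Cxcl10, Cx3cr1, Cd274, Arg1, Spp1 and Il1b (myeloid) and Ifng, Gzmb, Pdcd1, Cxcr3, Cxcr6 and Ctla4 (lymphoid) were named whatever their value. Genes with at most 3 UMIs in a class were left out of the folds given, because a fitted fold then depends on the prior count.

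Neutrophil-like cells and conventional DC-like cells were too few under the main filter. Their comparisons used the wider filter of at least 1000 UMIs and 500 genes, a choice made after the cells were counted. Activated DC-like against conventional DC-like cells had under 20 cells in a tumour and was not tested. The region comparison was planned only if a source said which spatial code marks which region. No source used here does, so it was not run. Differences between the tumours within a class are given without a test, as CPM with exact Poisson intervals, for classes of at least 100 cells, with genes of at least 50 UMIs and a ratio of at least 2 counted and the 5 largest ratios named. Shares carry exact Clopper-Pearson intervals. All intervals are at 95% and cover counting error only, and in folds given as at least a value a count of 0 was read as 3 counts over the class. Codes were assigned by a rule chosen after the data were seen. Each code's log2 count was centred on the mean of the cell's codes, and then on that code's median over the tumour's cells. The largest of these ratios had to lead the next by 0.5 (log2) with at least 50 code UMIs. A cell assigned to a code thus held relatively more of it than the tumour's typical cell, and not always most of its code UMIs.

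Alternatives were DESeq2 1.42.0 (size factors within edgeR, and its Wald test), no filter on low counts, no tumour block, each tumour alone, counts split at random between clustering and test, free RNA subtracted at an assumed 10% of each sum, resolutions 0.5 and 2, wider cell filters, mitochondrial limits of 5% and 20%, doublets kept, and scaling over both tumours together. Barcodes with 1 to 20 UMIs gave the free RNA profile and held 2.37% of gene UMIs in replicate 1 and 1.66% in replicate 3. The 10% was not estimated from the data. For macrophage-like cells of replicate 3 it is more than Col1a1 allows (4.12 CPM, against 531 in these barcodes). In replicate 1 (9.19 against 27.5 CPM) Col1a1 sets no such limit. Genes that share reads with near-identical copies, such as histone, H2-Q and Hspa1a with Hspa1b family members, are uncertain because the handling of such reads is not known. Some genes of the lists and of the named set are not reported here.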

Results

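The series concerns how differences among the cancer cells of a tumour go with the spatial arrangement of its immune cells. Single-cell RNA counts and spatial code counts were analysed for leukocytes sorted from 2 mosaic squamous cell carcinomas of the mouse, replicate 1 and replicate 3, which form 1 group. Replicate 1 held 89040909 gene UMIs and gave 3696 called cells with a median of 18766 UMIs and 3982.5 genes per cell. Replicate 3 held 170328781 gene UMIs and gave 5341 called cells with a median of 23412 UMIs and 4316 genes per cell. With 1 group, the comparisons that the design allows are between cell classes of the same tumours, between cells of different spatial codes, and between the tumours, and only those between classes carry a test.

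Macrophages dominated the immune cells of both tumours. Macrophage-like cells made up 60.2% of called cells in replicate 1 (2225 cells, interval 58.6 to 61.8) and 58.0% in replicate 3 (3099 cells, 56.7 to 59.4), a mean of 59.1% ± 1.54 (SD, n = 2). Monocyte-like cells, the blood-derived precursors of many tissue macrophages, made up 5.74% (5.01 to 6.53) and 9.10% (8.34 to 9.90), or 7.42% ± 2.38. At clustering resolution 2 these were 5.49% and 2.60%, so the order of the tumours depends on the clustering. NK-like cells made up 2.94% ± 0.286 (116 and 146 cells) and T-like cells 2.99% ± 0.482 (98 and 178 cells), of which CD8 T-like cells were 1.81% ± 0.645 and regulatory T-like cells 1.18% ± 0.164 of all cells. Plasmacytoid DC-like cells, a type known for type I interferon production, were 0.325% of replicate 1 (12 cells, 0.168 to 0.566) and 2.77% of replicate 3 (148 cells, 2.35 to 3.25). At a mitochondrial limit of 5% these shares were close, at 0.918% (20 cells) and 1.01% (47 cells). At every other cell setting replicate 1 held 12 such cells and replicate 3 held 147 to 159. The cDC1-like class, which takes up and cross-presents antigen, held 16 and 38 cells, and a fibroblast-like class of 28 and 37 cells passed the CD45 sort. The genes leading the regulatory T-like cluster included S100a9 and S100a8, which are abundant in neutrophils. Clusters left unnamed held 989 cells (26.8%) and 1209 cells (22.6%). The largest among the mononuclear phagocytes were led by Mgl2 and Asgr2 (345 and 207 cells), Fcna and Cbr2 (151 and 359 cells) and Atp6v0d2 and Mmp9 (45 and 376 cells), and S100a8 and S100a9 led another of 185 and 13 cells. A further unnamed cluster of 160 and 117 cells was led by the T cell genes Ikzf2, Tnfrsf4, Trbc2 and Cd3e, while phagocyte and DC markers scored 0.869 in it against 0.658 for T and NK markers. Its cells are not part of the T-like share, although Ikzf2 and Tnfrsf4 are among the markers of the regulatory T-like class.

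The UMI minimum, 5701 in replicate 1 and 9218 in replicate 3, bears on this makeup, since lymphocytes and neutrophils are known to hold little RNA. Among barcodes that passed only the wider filter of 1000 UMIs and 500 genes, Cd3e, a subunit of the T cell receptor complex, was detected in 30.8% in replicate 1 (323 of 1049, interval 28.0 to 33.7, median 3051 UMIs) and 51.3% in replicate 3 (609 of 1186, 48.5 to 54.2, median 5403 UMIs). Among cells that passed both filters the shares were 6.56% (median 18603 UMIs) and 7.23% (median 23219 UMIs). Under the wider filter (4632 and 6371 cells) T-like cells came to 9.19% ± 1.18, regulatory T-like cells to 4.92% ± 0.829 and macrophage-like cells to 48.5% ± 10.8 (SD, n = 2). Clusters were named anew there, with 255 and 276 regulatory T-like cells against 48 and 57 under the main filter. How much of that rise came from cells unnamed under the main filter was not tested. Neutrophil-like cells at the wider filter made up 10.0% of replicate 1 (464 cells, 9.17 to 10.9) and 0.753% of replicate 3 (48 cells, 0.556 to 0.998). The clusters that hold them had a median UMI count of 0.152 and 0.130 of their samples' medians. Small clusters seen at this filter carried markers of mast cells and basophils (Mcpt4, Tpsab1 and Cpa3; 24 and 0 cells) and of B cells (Igkc, Cd79a and Ms4a1; 17 and 11 cells). Both stayed unnamed because markers of another class scored high in them.

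**Figure D1:**
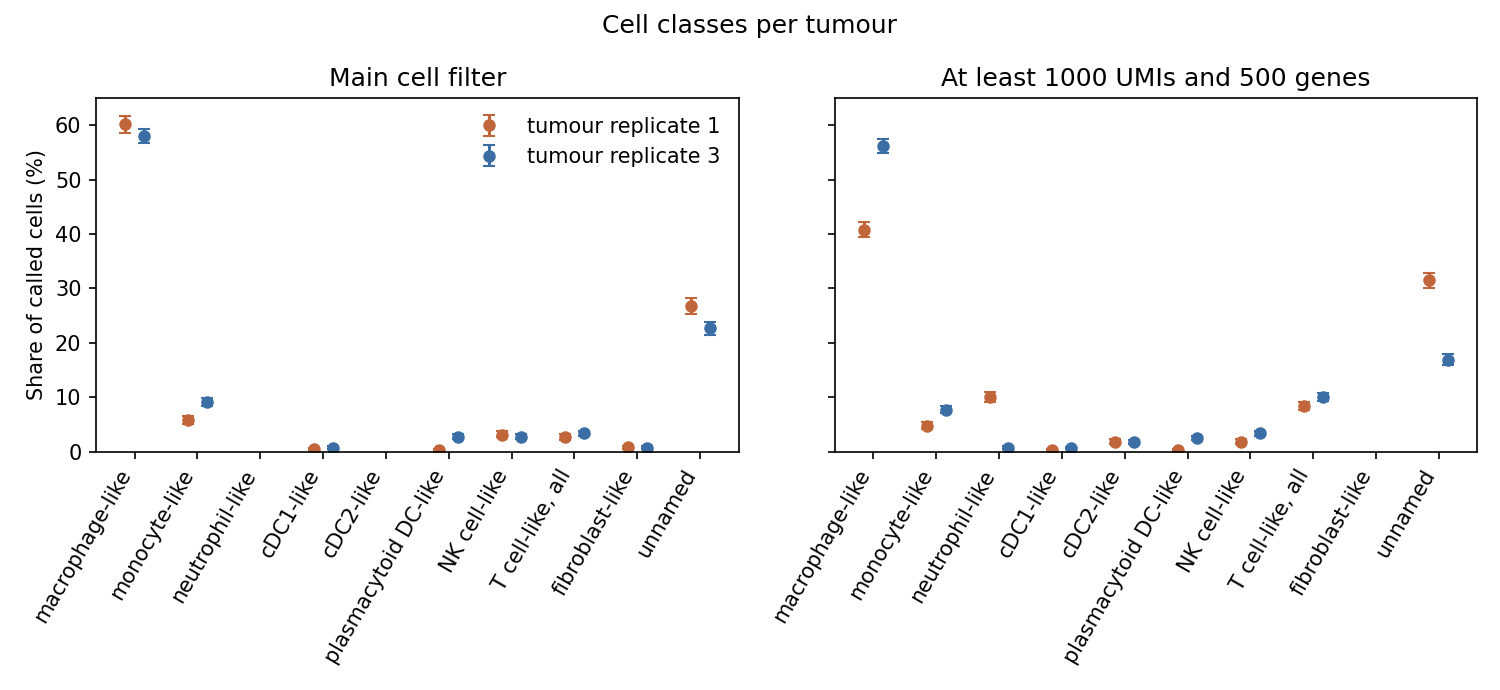
Share of called cells (%, vertical axis) in each cell class (horizontal axis) for each tumour, with the main cell filter in one panel and the wider filter in the other, points for single tumours and bars for exact 95% counting intervals. Macrophage-like cells lead in both tumours, and neutrophil-like cells are seen at the wider filter, at 10.0% in replicate 1 and 0.753% in replicate 3.

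Macrophage-like cells were set against monocyte-like cells to describe the myeloid compartment within the tumours. The chemokine Ccl8 was higher in macrophage-like cells by 5.42 ± 0.643 on the log2 scale (781 against 18.9 CPM; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00172). The eosinophil-attracting chemokine Ccl24 was lower there at -5.55 ± 0.249 (5.89 against 283 CPM). Gas6, a bridge between dying cells and the receptors that engulf them, rose by 5.08 ± 0.422, and Folr2, a folate receptor of resident macrophages, by 4.09 ± 0.302. Of 8171 genes tested, 275 were higher and 96 lower in macrophage-like cells, with the same direction in both tumours for 371 of 371. Fold changes come from the scaled fit and CPM are plain means over the tumours, so their ratios can differ.

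Genes of the cell cycle formed the largest group. Of 20 members tested, 17 rose, 0 fell and 3 did not pass (19 rose and 0 fell adjusted over the list alone, and DESeq2's Wald test called 17 and 0). The mitotic gene Cenpf (5.32 ± 0.764), the survivin gene Birc5 (4.88 ± 0.550) and the topoisomerase gene Top2a (4.85 ± 0.417; 118 against 3.79 CPM) were among them. The macrophage-like class included 3 clusters led by cycle genes, which held 4.27%, 3.55% and 2.43% of its cells in replicate 1 and 8.0%, 14.2% and 6.87% in replicate 3, whereas the monocyte-like class was 1 cluster. The rise of the cell cycle list thus depends on the class into which these clusters were named. Of the lipid handling and lysosome list, 8 of 18 rose and 0 fell (10 and 1 adjusted over the list alone; 11 and 1 at an unadjusted p under 0.05). The tetraspanin Cd63 was at 2.97 ± 0.303, the acid phosphatase Acp5 at 2.50 ± 0.559 and the cholesterol exporter Abca1 at 1.90 ± 0.293. Of the alternative activation and tissue repair list, 7 of 18 rose and 3 fell (7 and 3 adjusted over the list alone). Beside Gas6 and Folr2, the growth factor Igf1 rose by 3.00 ± 0.680, while the matrix proteins Thbs1 (-3.23 ± 0.541; 34.5 against 256 CPM) and Fn1 (-1.82 ± 0.334; 529 against 1924 CPM) and the cytokine Tgfb1 (-0.94 ± 0.202) fell. Among myeloid-attracting chemokines 2 of 13 rose, Ccl8 and the platelet factor Pf4 (2.26 ± 0.477), and 1 fell (2 and 1 adjusted over the list alone).

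Inflammatory cytokine and checkpoint ligand genes that passed lay on the monocyte-like side. Among checkpoint ligands and costimulation genes 3 of 15 fell and 0 rose (4 and 0 adjusted over the list alone; 4 fell and 1 rose at an unadjusted p under 0.05, and the Wald test called 3 and 0). They were Pdcd1lg2, a ligand of PD-1 (-1.53 ± 0.349), the T cell costimulator Cd80 (-1.36 ± 0.221) and Pvr (-0.96 ± 0.223). Of the checkpoint receptors and exhaustion list, 1 of 13 rose and 2 fell (2 and 2 adjusted over the list alone; 4 and 2 unadjusted; Wald 1 and 2; median log2 fold change of the list 1.99), the latter being Havcr2, which encodes TIM-3 (-1.35 ± 0.270), and the nuclear receptor Nr4a2 (-1.79 ± 0.269). Inflammatory cytokines had 2 of 11 lower and 0 higher (3 and 0 adjusted over the list alone; 4 and 0 unadjusted; Wald 1 and 0), the prostaglandin synthase Ptgs2 (-2.20 ± 0.494) and the interleukin Il18 (-1.31 ± 0.231). Interferon-stimulated genes had 2 of 20 lower and 0 higher (2 and 0 adjusted over the list alone; 3 and 1 unadjusted; Wald 2 and 0). These were the antiviral membrane protein gene Ifitm3 (-1.43 ± 0.257) and the nucleic acid sensor Zbp1 (-1.32 ± 0.190). In hypoxia and glycolysis 1 of 17 fell, the pyruvate kinase Pkm (-0.70 ± 0.160), and 0 rose (2 and 0 adjusted over the list alone; 4 and 0 unadjusted; Wald 2 and 0). Of naive and memory T cell genes 1 of 9 fell and 0 rose (2 and 0 adjusted over the list alone; 2 and 2 unadjusted; Wald 1 and 0). At the wider filter more members passed: 8 of 14 inflammatory cytokines and 5 of 15 checkpoint ligands were lower and 0 higher, and 6 of 21 interferon-stimulated genes were lower and 2 higher. There 2 of 8 T-cell-attracting chemokines and 4 of 15 Fc and pattern-recognition receptors were lower and 0 higher.

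In the remaining lists few or no genes passed. Of chemokine receptors 1 of 11 rose, Cxcr3 at 2.19 ± 0.528, and 0 fell (2 and 0 adjusted over the list alone, 2 and 0 unadjusted, Wald 1 and 0). The MHC class I list had 1 of 13 higher, H2-Q7 at 1.12 ± 0.194, and 0 lower (3 and 2 adjusted over the list alone, 3 and 3 unadjusted, Wald 1 and 2). The dissociation stress list had 2 of 14 higher, Hspa1b (1.51 ± 0.348) and Hspa1a (1.31 ± 0.307), and 0 lower (2 and 1 adjusted over the list alone, 2 and 1 unadjusted, Wald 0 and 0). In edgeR's test 0 genes passed in MHC class II presentation (10 tested; 0 unadjusted), cytotoxicity and T helper 1 (12; 0 unadjusted), T-cell-attracting chemokines (7; 1 higher unadjusted), T helper 2 and 17 (3; 1 higher unadjusted and adjusted over the list alone) and Fc and pattern-recognition receptors (15; 1 higher and 3 lower unadjusted). The Wald test also called 0 in each. Cxcl9, an interferon-induced attractant of T cells, had -1.13 ± 0.668 (adjusted p = 0.368 by the same test), with 0.00 in replicate 1 and -1.74 in replicate 3. It turned to 2.13 at resolution 2 and 1.35 with split counts, and passed as lower at the wider filter, at a mitochondrial limit of 5% and with no filter on low counts. Other genes named in advance did not pass either: Cxcl10 (-0.18 ± 0.398), the interleukin Il1b (-1.53 ± 0.784), the osteopontin gene Spp1 (-1.64 ± 0.905), the arginase Arg1 (-0.26 ± 0.305) and Cd274, which encodes PD-L1 (-0.64 ± 0.424). The fractalkine receptor Cx3cr1 (1.81 ± 0.520) passed over its list alone.

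**Figure D2:**
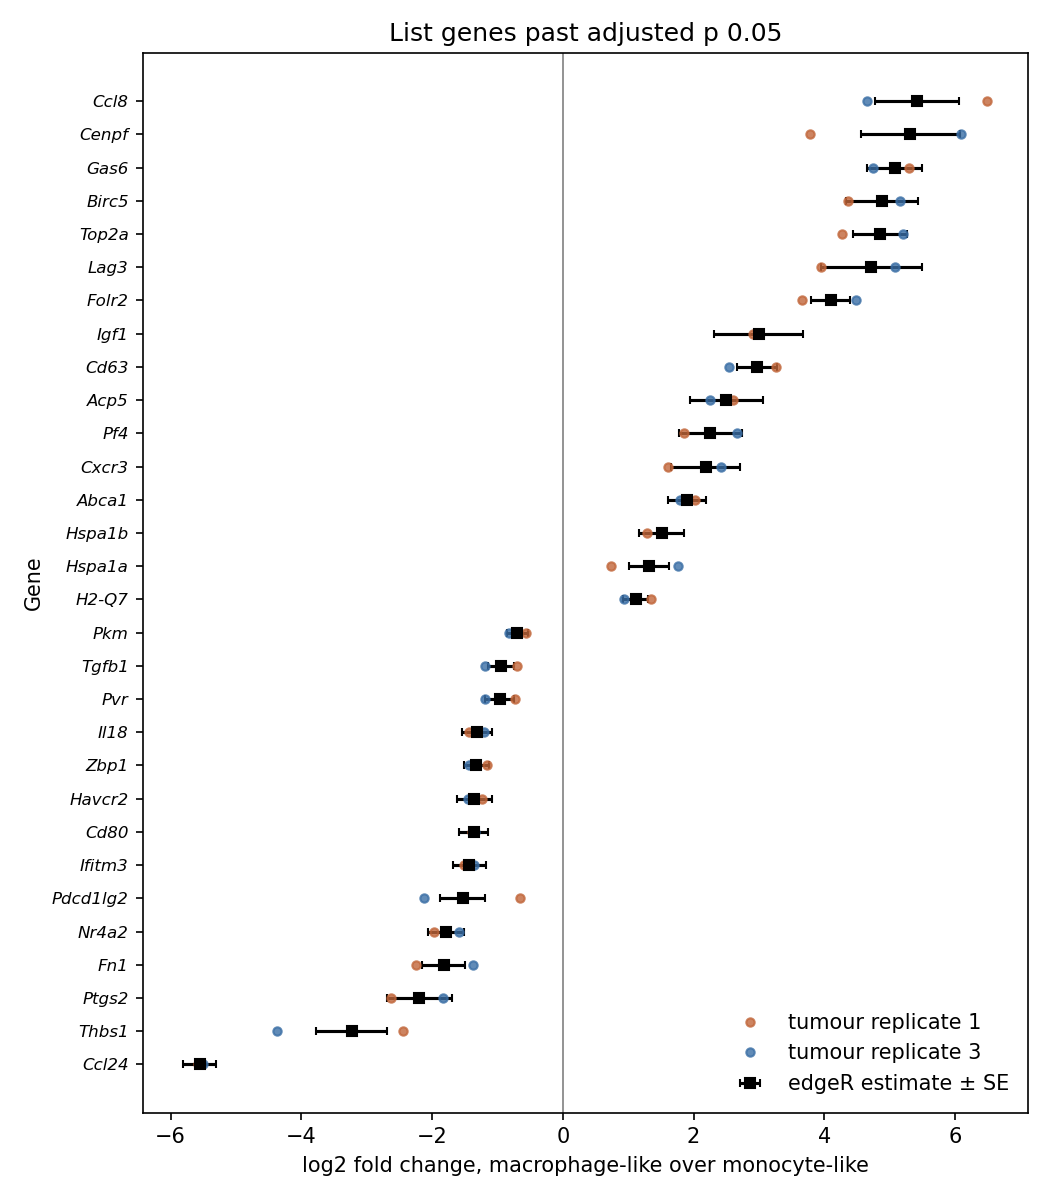
Log2 fold change of macrophage-like over monocyte-like cells (horizontal axis) for genes of the fixed lists past an adjusted p of 0.05 in edgeR's quasi-likelihood test, at most 3 per list and direction (vertical axis); black squares with bars are the estimates ± SE and coloured dots each tumour's own value. Cell cycle genes lie to the right, with Cenpf at 5.32, and Ccl24 lies farthest to the left at -5.55; Lag3 had at most 3 UMIs in a class, so its fold depends on the prior count.

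The call count rests on the tumour block, without which 8 genes were higher and 1 lower, and fell to 67 and 9 with expected free RNA subtracted. DESeq2's Wald test called 287 higher and 238 lower, which moved the higher share of calls from 74.1% to 54.7%.

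Conventional DC-like cells (cDC1-like and cDC2-like, at the wider filter) were set against macrophage-like cells to separate antigen presentation from scavenging. Antigen presentation genes were higher on the DC side: of 10 MHC class II genes 7 rose and 0 fell (9 and 0 adjusted over the list alone, 9 and 0 unadjusted, Wald 4 and 0). The MHC class II gene H2-DMb2 was among the markers that named cDC2-like cells, and split counts had no value here. The direction of this list is thus not independent of the naming. The peptide-loading modulator H2-Oa was at 5.82 ± 0.286 (223 against 4.43 CPM; edgeR quasi-likelihood test, adjusted p = 3.14e-09) and Ciita, the master regulator of MHC class II, at 2.23 ± 0.197. Ccl17, which attracts Ccr4-bearing T cells, rose by 6.36 ± 0.757 (293 against 4.24 CPM), and Ccr6 by 5.16 ± 0.432. Scavenging and repair genes were higher in macrophage-like cells. Arg1 was at -3.20 ± 0.549 (48.0 against 493 CPM) and Cd63 at -3.11 ± 0.316 (102 against 1017 CPM). Of 7907 genes tested 468 were higher and 395 lower in DC-like cells, with the same direction in both tumours for 862 of 863.

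MHC class I presentation had 4 of 13 genes higher and 0 lower (5 and 0 adjusted over the list alone, 6 and 0 unadjusted, Wald 4 and 0). The immunoproteasome subunits Psmb8 (1.24 ± 0.259) and Psmb9 (1.23 ± 0.245) and the peptide transporter Tap1 (1.02 ± 0.209) were among them. Checkpoint ligands and costimulation genes had 9 of 15 higher and 3 lower (9 and 5 adjusted over the list alone). Pdcd1lg2 was at 3.08 ± 0.372, Tnfsf4, the OX40 ligand, at 3.35 ± 0.914 and Tnfsf9, the 4-1BB ligand, at 2.48 ± 0.370. The B7-H3 gene Cd276 was at -2.93 ± 0.409. Checkpoint receptors had 4 of 13 higher, among them Tnfrsf18 (4.41 ± 0.314) and Nr4a2 (2.71 ± 0.299), and 1 lower (5 and 1 adjusted over the list alone). Inflammatory cytokines had 4 of 14 higher and 2 lower (4 and 2 adjusted over the list alone). Il1b was at 1.48 ± 0.407 and Il18 at -1.02 ± 0.267. Of the alternative activation and tissue repair list 12 of 19 fell and 1 rose, the elastase gene Mmp12 at 2.66 ± 0.518 (14 fell and 1 rose adjusted over the list alone). Lipid handling and lysosome genes had 12 of 18 lower and 0 higher (14 and 1 adjusted over the list alone, 14 and 1 unadjusted, Wald 11 and 0). Abca1 was at -3.01 ± 0.311 and the cathepsin Ctsk at -3.00 ± 0.487. Fc and pattern-recognition receptors had 11 of 15 lower and 1 higher (11 and 1 adjusted over the list alone). The RNA sensor Tlr7 was at -3.54 ± 0.470 and Itgax, the integrin CD11c, at 2.35 ± 0.275. Myeloid-attracting chemokines had 7 of 12 lower and 1 higher (7 and 1 adjusted over the list alone). Ccl8 was at -3.97 ± 0.524 and Ccl24 at 1.84 ± 0.317.

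Cell cycle genes had 8 of 20 lower and 0 higher (8 and 1 adjusted over the list alone, 10 and 1 unadjusted, Wald 4 and 0). The thymidine kinase Tk1 was at -1.81 ± 0.283. Chemokine receptors had 3 of 11 higher and 1 lower, Cx3cr1 at -2.86 ± 0.356 (3 and 3 adjusted over the list alone). Naive and memory genes had 2 of 9 higher, among them the chromatin organiser Satb1 (3.22 ± 0.482), and 1 lower (2 and 1 adjusted over the list alone). Hypoxia and glycolysis had 1 of 17 higher, Ndrg1 (1.72 ± 0.208), and 1 lower, the mitophagy receptor Bnip3 (-1.66 ± 0.291), in either adjustment. The single calls of other lists were Ccl17 (T-cell-attracting chemokines, 7 tested), Ifi205 (interferon-stimulated genes, 21 tested; 5.53 ± 0.372), Tbx21 (cytotoxicity and T helper 1, 13 tested; 3.25 ± 0.813), Nr4a1 (dissociation stress, 14 tested; 1.40 ± 0.307). Maf was the single lower call of T helper 2 and 17 (5 tested; -3.13 ± 0.330). Adjusted over the list alone these counts stayed at 1, with 1 further chemokine lower. Cxcl9 (0.13 ± 0.338), Cxcl10 (-0.57 ± 0.476), Spp1 (-0.32 ± 0.652) and Cd274 (0.20 ± 0.384) did not pass. Without the tumour block 207 genes were higher and 168 lower, and with an assumed 10% of free RNA subtracted 294 and 236.

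Neutrophil-like cells (464 in replicate 1 and 48 in replicate 3, at the wider filter) were set against monocyte-like cells (218 and 493) to compare the recruited myeloid classes. Neutrophil-like cells carried high inflammatory transcripts and more of some chemokines: Cxcl2, a neutrophil attractant, was at 27717 against 2691 CPM (4.05 ± 0.560 on the log2 scale) and Il1b at 11700 against 1231 CPM (3.87 ± 0.459). The iron-binding lipocalin Lcn2 was at 350 against 0.873 CPM (9.22 ± 0.409; edgeR quasi-likelihood test, adjusted p = 1.72e-07). Acod1, which makes itaconate, rose by 6.43 ± 0.444 and the interleukin subunit Il23a by 6.74 ± 0.629. The MHC class II machinery was lower, with Ciita at -4.30 ± 0.469 and the peptide-exchange subunit H2-DMa at -3.77 ± 0.398. Of 7804 genes tested 1066 were higher and 1831 lower, and 2667 of the 2897 had the same direction in both tumours.

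Inflammatory cytokines had 11 of 14 higher and 0 lower (the same adjusted over the list alone, unadjusted and in the Wald test), Lcn2, Il23a, Acod1 and Il1b among them. Hypoxia and glycolysis genes had 8 of 17 higher and 0 lower (8 and 0 adjusted over the list alone, 10 and 0 unadjusted, Wald 8 and 0). Among them were the oxygen sensor Egln3 (3.73 ± 0.369), Ankrd37 (2.16 ± 0.300) and the glucose transporter Slc2a1 (2.12 ± 0.362). MHC class II genes had 8 of 10 lower and 0 higher by every one of these counts. MHC class I presentation had 3 of 13 higher and 2 lower (3 and 2 adjusted over the list alone). H2-Q7 was at 1.11 ± 0.316 and the immunoproteasome subunit Psmb10 at -2.01 ± 0.278. Fc and pattern-recognition receptors had 6 of 15 higher and 4 lower (7 and 4 adjusted over the list alone). The lipopolysaccharide co-receptor Cd14 was at 3.08 ± 0.411, the scavenger receptor Msr1 at -2.54 ± 0.417 and the lysozyme Lyz2 at -2.20 ± 0.368. Myeloid-attracting chemokines had 5 of 12 higher and 4 lower. Ccl2, a monocyte attractant, was at -2.95 ± 0.395. T-cell-attracting chemokines had 2 of 8 higher, Ccl3 (4.90 ± 0.749) and Ccl4 (4.62 ± 0.672), and 2 lower, Cxcl9 (-5.52 ± 0.558; 18.8 against 684 CPM) and Cxcl16 (-1.27 ± 0.292). Both counts were the same in either adjustment, but Cxcl16 turned to 0.93 at 500 UMIs and 300 genes. Checkpoint ligands and costimulation genes had 4 of 15 higher, including Cd274 (2.69 ± 0.411), and 3 lower, including Cd86 (-1.41 ± 0.279), also in either adjustment.

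Chemokine receptors had 4 of 11 higher, led in abundance by Ccr1 (2.76 ± 0.403; 1664 against 364 CPM), and 2 lower, Cx3cr1 (-2.50 ± 0.489) among them, in either adjustment. Interferon-stimulated genes had 5 of 21 higher, such as Isg15 (3.38 ± 0.494), and 3 lower, such as Zbp1 (-3.25 ± 0.546), with 6 and 3 adjusted over the list alone. Lipid handling and lysosome genes had 6 of 18 higher, among them the lipid droplet coat Plin2 (2.41 ± 0.535), and 3 lower (8 and 5 adjusted over the list alone). The lower members were the progranulin Grn (-1.48 ± 0.247), the cholesterol carrier Npc2 (-1.23 ± 0.217) and Lamp1 (-0.85 ± 0.254). Alternative activation genes had 2 of 18 higher and 5 lower (2 and 6 adjusted over the list alone). Il1rn, the interleukin-1 receptor antagonist, was at 2.90 ± 0.425 and Fn1 at -3.82 ± 0.683. Dissociation stress genes had 5 of 14 higher and 0 lower (5 and 0 adjusted over the list alone, 9 and 0 unadjusted, Wald 7 and 0), including the early growth response gene Egr1 (3.22 ± 0.524) and Dusp1 (2.38 ± 0.349). Checkpoint receptors had 2 of 13 higher and 1 lower, naive and memory genes 3 of 9 higher (Klf2 and Satb1 among them) and 2 lower, and cell cycle genes 2 of 20 higher and 3 lower. Adjusted over the list alone these were 2 and 1, 3 and 3, and 1 and 3. Cytotoxicity and T helper 1 had 1 of 13 higher, Tnf at 1.90 ± 0.336, and T helper 2 and 17 had 1 of 5 lower, Maf at -1.49 ± 0.446, in either adjustment. Cxcl10 (-0.26 ± 0.564), Spp1 (-0.63 ± 0.679) and Arg1 (-1.48 ± 0.611) did not pass.

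Neutrophil-like values rest on shallow cells and mostly on replicate 1. The median over all genes was -0.44 on the log2 scale, against -0.30 with DESeq2's size factors and -0.24 with its Wald test. The size factors gave 1265 higher and 1503 lower (45.7% higher against 36.8% with the main scaling) and the Wald test 1302 and 1300. At 500 UMIs and 300 genes 594 were higher and 1085 lower. There the neutrophil-like class held 472 and 47 cells, and the monocyte-like class 43 and 189 instead of 218 and 493.

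CD8 T-like cells were set against regulatory T-like cells to compare these T cell classes of the same tumours. The CD8 T-like class joined a cluster led by Ly6c2, Dapl1 and Ccr7, with a Cd8a UMI in 11 of 30 cells of replicate 1 and 49 of 67 of replicate 3, and a cluster led by Csf2 and Penk. The latter had a Cd8a UMI in 14 of 20 and 40 of 54 cells and a Cd4 UMI in 7 of 20 and 18 of 54. In the largest NK-like cluster 1 of 38 and 0 of 47 cells had a Cd4 UMI, so the CD8 T-like class is probably not CD8 T cells alone. The chemokine Ccl1 was higher in CD8 T-like cells by 6.55 ± 0.964 (825 against 14.4 CPM; edgeR quasi-likelihood test, adjusted p = 0.0131). Also higher were Cd160, a receptor of cytotoxic lymphocytes (4.38 ± 0.656), Tcf7, which encodes the memory factor TCF1 (3.75 ± 0.435), the interferon gene Ifng (3.24 ± 0.537) and the death ligand Fasl (2.98 ± 0.374). Regulatory T-like cells carried more of the inhibitory receptor Ctla4 (-2.45 ± 0.266; 160 against 955 CPM), of the costimulatory receptors Tnfrsf18 (-1.89 ± 0.238) and Icos (-1.79 ± 0.285), and of the granzyme Gzmb (-2.91 ± 0.461; 112 against 1045 CPM). Of 8171 genes tested 79 were higher and 27 lower, with the same direction in both tumours for 106 of 106.

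Cytotoxicity and T helper 1 genes had 4 of 12 higher and 1 lower (5 and 1 adjusted over the list alone), and checkpoint receptors 1 of 13 higher and 3 lower (3 and 6 adjusted over the list alone). Naive and memory genes had 2 of 9 higher and 0 lower (5 and 1 adjusted over the list alone, 5 and 1 unadjusted, Wald 3 and 0). Cell cycle genes had 4 of 20 lower and 0 higher (13 and 0 adjusted over the list alone, 14 and 0 unadjusted, Wald 7 and 0). The proliferation marker Mki67 was at -3.43 ± 0.557 and Top2a at -2.14 ± 0.407. Hypoxia and glycolysis genes had 2 of 17 lower, Bnip3 (-2.61 ± 0.388) and Pkm (-1.20 ± 0.164), and 0 higher (10 and 0 adjusted over the list alone, 10 and 0 unadjusted, Wald 7 and 0). T helper 2 and 17 had 1 of 3 lower, Maf (-3.05 ± 0.395), and 0 higher (2 and 0 adjusted over the list alone, 2 and 0 unadjusted, Wald 1 and 0). Alternative activation had 1 of 18 lower, Stab1 (-2.15 ± 0.454), and 0 higher (2 and 0 adjusted over the list alone, 3 and 0 unadjusted, Wald 3 and 0). Lipid handling had 1 of 18 higher, the galectin Lgals3 (1.80 ± 0.375), and 0 lower (1 and 6 adjusted over the list alone, 1 and 6 unadjusted, Wald 1 and 1).

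In edgeR's test 0 genes passed in the other lists, where counts at an unadjusted p under 0.05, those adjusted over the list alone and those of the Wald test were as follows. Interferon-stimulated genes had 1 higher and 7 lower unadjusted, 0 and 7 over the list alone and 0 and 1 by Wald. MHC class I genes had 1 and 3, 0 and 3, and 0 and 1, chemokine receptors 0 and 3, 0 and 2, and 0 and 1, and myeloid-attracting chemokines 1 and 4, 1 and 4, and 0 and 4. Dissociation stress genes had 3 and 1, 1 and 0, and 0 and 0, and inflammatory cytokines 0 and 5, 0 and 0, and 0 and 1. Checkpoint ligands had 2 and 1 unadjusted, Fc and pattern-recognition receptors 0 and 2, and T-cell-attracting chemokines and MHC class II 0 and 0, with 0 in both further counts. Pdcd1, which encodes PD-1, was at 1.18 ± 0.377 (101 against 51.4 CPM) and passed over its list alone, while Cxcr3 (-0.45 ± 0.309) and Cxcr6 (0.27 ± 0.348) did not pass.

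Cycle genes in this comparison changed direction with the cell filter, the mitochondrial limit and the resolution. A cluster of 43 dividing cells (12 and 31) scored 0.667 for NK cells and 0.641 for CD8 T cells and was named NK-like. At the wider filter the dividing cluster was named CD8 T-like, both classes gained cells, and the list turned to 19 higher and 0 lower. At resolution 2, where the CD8 T-like class held 36 and 81 cells, Ccna2, Mki67 and Top2a turned to 1.33, 1.24 and 1.66, and at a mitochondrial limit of 5% to 11.60, 2.78 and 3.03. What turned them was not tested. Calls were few without the tumour block (2 higher and 1 lower) and with counts split between clustering and test (8 higher and 0 lower; 227 and 345 at an unadjusted p under 0.05). They were also few at a mitochondrial limit of 5% (9 and 2) and at resolutions 0.5 (10 and 10) and 2 (9 and 7), where 6, 13 and 15 of the 106 genes kept their call. The Wald test called 114 higher and 88 lower (56.4% higher against 74.5%).

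NK-like cells were set against CD8 T-like cells to compare the cytotoxic lymphocytes. Ccl1 (-5.23 ± 0.750; 23.2 against 825 CPM; edgeR quasi-likelihood test, adjusted p = 0.0245) and the tissue-retention receptor Cxcr6 (-3.23 ± 0.383; 40.3 against 361 CPM) were lower in NK-like cells. Adjusted over the list alone, unadjusted and by the Wald test, the cell cycle list had the most calls. Adjusted over all genes, checkpoint receptors had the most, with 6 of 13 lower and 0 higher (9 and 0 adjusted over the list alone, 9 and 0 unadjusted, Wald 6 and 0). Havcr2 (-3.32 ± 0.485), Pdcd1 (-2.82 ± 0.388), the ectonucleotidase Entpd1 (-2.77 ± 0.479), Icos (-2.68 ± 0.312) and Ctla4 (-2.14 ± 0.282) were among them. Of 8171 genes tested 14 were higher and 11 lower, and 25 of 25 had the same direction in both tumours.

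Cell cycle genes had 4 of 20 higher and 0 lower (16 and 0 adjusted over the list alone, 16 and 0 unadjusted, Wald 9 and 0). They were Ccna2 (3.79 ± 0.619), Mki67 (3.77 ± 0.540), Cdk1 (2.88 ± 0.420) and Top2a (2.73 ± 0.396). These calls were lost without the dividing cluster, in which the list took 1.41% of UMIs against 0.152% to 0.614% in the other named T and NK clusters. In it 13 of 31 cells of replicate 3 and 0 of 12 of replicate 1 had a Cd8a UMI. Without that cluster Ccna2 was at -1.65, Cdk1 at -0.98, Top2a at -0.31 and Mki67 at 0.54, and at the wider filter 16 of 20 members were lower and 0 higher. The chemokine receptor list had 1 of 11 lower, Cxcr6, and 0 higher (5 and 0 adjusted over the list alone, 5 and 0 unadjusted, Wald 3 and 0). Naive and memory genes had 1 of 9 lower, the interleukin-7 receptor Il7r (-2.67 ± 0.472), and 0 higher (5 and 0, 6 and 0, and 3 and 0 by the same counts). Cytotoxicity and T helper 1 had 1 of 12 lower, Ccl1, and 0 higher (3 and 5 adjusted over the list alone, 3 and 5 unadjusted, Wald 0 and 0). Outside the lists, the kinase gene Lrrk1 (2.66 ± 0.438) and Alad, a haem synthesis enzyme (1.41 ± 0.196), rose. Ifng (-1.31 ± 0.400), Gzmb (1.47 ± 0.439) and Cxcr3 (-1.46 ± 0.318) did not pass over all genes.

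In edgeR's test 0 genes passed in the other 13 lists. Unadjusted, these had 0 higher and 3 lower for T-cell-attracting chemokines, 0 and 5 for checkpoint ligands, 0 and 1 for myeloid-attracting chemokines, 0 and 2 for T helper 2 and 17, 1 and 1 for interferon-stimulated genes, 0 and 0 for MHC class II and 0 and 2 for MHC class I. They were 2 and 1 for alternative activation, 2 and 1 for inflammatory cytokines, 1 and 0 for hypoxia and glycolysis, 3 and 3 for lipid handling, 0 and 0 for Fc receptors and 0 and 1 for dissociation stress. The Wald test called 1 lower for checkpoint ligands, 1 higher for alternative activation, 1 and 1 for inflammatory cytokines and 0 in the rest. Adjusted over the list alone, T-cell-attracting chemokines and checkpoint ligands each had 3 lower and lipid handling 2 and 2. Interferon-stimulated genes and alternative activation then had 1 higher, inflammatory cytokines 1 and 1, and myeloid-attracting chemokines, T helper 2 and 17 and dissociation stress each had 1 lower. Calls fell to 0 and 0 in edgeR without the tumour block (359 and 194 at an unadjusted p under 0.05) and with expected free RNA subtracted (473 and 306), while the Wald test called 38 and 29.

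T-like cells were set against mononuclear phagocyte-like cells as a check between distant lineages. T-like cells carried the chemokine Ccl1 (11.50 ± 0.455), Gzmb (9.65 ± 0.368; 551 against 0.592 CPM; edgeR quasi-likelihood test, adjusted p = 2.27e-05), Ifng (9.16 ± 0.485) and Xcl1, which attracts cDC1 cells (9.12 ± 0.405). Mononuclear phagocyte-like cells carried the high-affinity Fc receptor Fcgr1 (-6.57 ± 0.807), Ccl2 (-6.05 ± 0.422), Arg1 (-5.94 ± 0.447; 6.63 against 506 CPM) and the MHC class II chain H2-Ab1 (-5.65 ± 1.08; 121 against 5960 CPM). Of 8297 genes tested 944 were higher and 1676 lower in T-like cells, and 2618 of 2620 had the same direction in both tumours.

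Cytotoxicity and T helper 1 genes had 11 of 12 higher and 0 lower (11 and 1 adjusted over the list alone, 11 and 1 unadjusted, Wald 11 and 0). Checkpoint receptors had 10 of 13 higher and 1 lower. Ctla4 was at 8.63 ± 0.329, Pdcd1 at 7.64 ± 0.479 and Entpd1 at -0.80 ± 0.205. Naive and memory genes had 6 of 9 higher and 0 lower (6 and 1 adjusted over the list alone, 6 and 1 unadjusted, Wald 5 and 0), with Lef1 at 7.47 ± 0.402. T helper 2 and 17 had 2 of 2 higher, Il10 (3.45 ± 0.656) and Maf (0.53 ± 0.147). MHC class I presentation had 7 of 13 higher and 0 lower (7 and 0 adjusted over the list alone, 8 and 0 unadjusted, Wald 8 and 0). The trans-activator Nlrc5 was at 1.02 ± 0.258. On the phagocyte side, Fc and pattern-recognition receptors had 15 of 15 lower, lipid handling and lysosome genes 17 of 19 lower and 0 higher, each in every count. Alternative activation genes had 14 of 18 lower and 0 higher (16 and 0 adjusted over the list alone, 16 and 0 unadjusted, Wald 15 and 0). MHC class II genes had 8 of 10 lower and 2 higher, H2-Oa (2.27 ± 0.537) and the lipid-presenting Cd1d1 (1.85 ± 0.592). Myeloid-attracting chemokines had 10 of 13 lower and 1 higher, Cx3cl1 (3.51 ± 0.633). T-cell-attracting chemokines had 4 of 7 lower, including Cxcl9 (-4.84 ± 0.869) and Cxcl10 (-2.31 ± 0.416), and 1 higher, Ccl5 (2.64 ± 0.621).

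Chemokine receptors had 5 of 11 higher, including Cxcr6 (8.37 ± 0.409), and 4 lower, including Cx3cr1 (-3.82 ± 0.695), and checkpoint ligands 3 of 15 higher, including Pdcd1lg2 (2.91 ± 0.260), and 9 lower, including the phagocytosis-restraining receptor Sirpa (-5.42 ± 0.502). Interferon-stimulated genes had 4 of 21 higher, such as Gbp4 (1.84 ± 0.211), and 6 lower, such as Ifitm3 (-2.96 ± 0.271), and inflammatory cytokines 3 of 10 higher, such as Csf1 (3.61 ± 0.355), and 6 lower, such as Il1b (-3.45 ± 0.731). Dissociation stress genes had 9 of 14 lower, with Fos at -3.19 ± 0.265, and 1 higher, Jund (0.84 ± 0.173). Hypoxia and glycolysis genes had 5 of 16 lower and 0 higher (4 and 0 adjusted over the list alone, 6 and 1 unadjusted, Wald 3 and 2). Cell cycle genes had 6 of 20 lower and 0 higher (6 and 0 adjusted over the list alone, 8 and 2 unadjusted, Wald 6 and 1), with the dividing lymphocyte cluster counted outside the T-like class. Adjusted over the list alone, interferon-stimulated genes had 5 higher and 6 lower and inflammatory cytokines 3 and 7, while checkpoint receptors, T helper 2 and 17, MHC class II, both chemokine lists, chemokine receptors, checkpoint ligands and dissociation stress kept their counts. Spp1 (-1.32 ± 0.741) and Cd274 (-0.08 ± 0.332) did not pass. DESeq2's size factors gave 1150 higher and 1467 lower (43.9% higher against 36.0%) and its Wald test 1245 and 1441 (46.4%), and the median over all genes was -0.15 on the log2 scale against -0.06 and -0.04. Without the tumour block 439 were higher and 1058 lower, and with split counts 560 and 961.

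The tumours were compared within macrophage-like, monocyte-like and NK-like cells, with no test because each tumour is 1 sample. Of 11723 genes with enough UMIs in macrophage-like cells 949 were at least 2-fold higher in replicate 1 and 571 in replicate 3. In monocyte-like cells these were 125 and 191 of 7786 genes, and in NK-like cells 79 and 192 of 5277. The tumours differed by sex-linked transcripts: in macrophage-like cells Xist, which is transcribed from the inactive X chromosome, had 25662 UMIs in replicate 1 and 13 in replicate 3. The Y-linked Ddx3y had 1 and 4749 UMIs and Kdm5d 0 and 617 (at least 104-fold higher in replicate 3). Xist differed likewise in monocyte-like cells (1930 against 2 UMIs) and NK-like cells (1686 against 1). Outside these, the largest ratios in macrophage-like cells were those of Gm5483 (60 against 1 UMIs) and Retnlg (110 against 3), which also led the unnamed S100a8 and S100a9 cluster, so RNA of neutrophils is not excluded there. The costimulatory receptor Tnfrsf9 was 50.4-fold higher in macrophage-like cells of replicate 1 (113 against 2.24 CPM) and the granzyme Gzmf 75.02-fold higher in its NK-like cells (541 against 7.21 CPM). In monocyte-like cells the lysozyme Lyz1 had 2 UMIs in replicate 1 (0.684 CPM, interval 0.0828 to 2.47) and 183 in replicate 3 (23.98 CPM, 20.6 to 27.7). Ccl17 had 3 (1.03 CPM, 0.212 to 2.998) and 199 (26.1 CPM, 22.6 to 29.96).

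Interferon-stimulated genes set the monocyte-like cells of the tumours apart: 16 of 20 members with enough UMIs were at least 2-fold higher in replicate 3 and 0 in replicate 1. Isg15 was at 52.7 and 224 CPM, and the interferon-induced chemokines Cxcl9 at 106 and 698 and Cxcl10 at 69.1 and 340. At resolution 2 the monocyte-like class held 203 cells of replicate 1 instead of 212, and 139 of replicate 3 instead of 486. The tumours were not compared at that resolution. In macrophage-like cells the interferon-stimulated list had 2 of 22 members higher in replicate 1 and 1 in replicate 3, with Isg15 at 92.4 and 103. Macrophage-like cells of replicate 1 instead had more alternative activation transcripts in 10 of 20 members and fewer in 1. Arg1 stood at 751 and 242 CPM, the elastase gene Mmp12 at 219 and 17.1, and the angiogenic factor Vegfa at 220 and 83.1. Hypoxia and glycolysis genes were higher there in 8 of 17 and lower in 0, with Bnip3 at 198 and 67.5 CPM and Slc2a1 at 152 and 57.7. Lipid and lysosome genes were higher in 9 of 20 and lower in 1, with Fabp5 at 1087 and 355 CPM. Arg1 was also higher in monocyte-like cells of replicate 1 (1073 and 240 CPM). Macrophage-like cells of replicate 3 had more cell cycle transcripts (19 of 20 higher, 0 lower; Top2a 54.4 and 181 CPM) and Spp1 (260 and 987). In NK-like cells of replicate 3 the T-cell-attracting chemokines were higher in 4 of 4 members. Ccl3 was at 3.66 and 42.5 CPM and Ccl5 at 102 and 259, and Ifng stood at 22.6 and 113. In the same cells 2 of 12 dissociation stress genes were higher in replicate 3 and 0 in replicate 1, with a median log2 ratio of -0.74 (replicate 1 over replicate 3). Ccl8, picked after its values were seen, was at 10.4 and 45.9 CPM. The class also held the dividing cluster, with a Cd8a UMI in 0 of 12 cells of replicate 1 and 13 of 31 of replicate 3. Stress, free RNA and that cluster were not tested as sources of these changes in NK-like cells.

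Many macrophage-like cells lay in clusters held mostly by 1 tumour, but not all. A cluster led by Fxyd2 and Col14a1 held 284 and 492 cells, or 12.8% and 15.9% of the class. A cluster led by Hmox1, Fbxo32 and Mt2 held 863 cells of replicate 1 and 9 of replicate 3, and a cluster led by Vcam1, Gdf15 and Hes1 held 600 and 78. A cluster led by Il18bp and Gbp2b held 21 and 701, a histone-led cluster 79 and 440, and a cluster led by Cyp4f18 and Pdpn 44 and 450. Among NK-like cells the dividing cluster held 12 and 31 cells, which brought Cd8a and Cd8b1 into the class in replicate 3, and a cluster led by Tmem176a and Krt83 held 44 and 12. Median depths were 18484 and 24272 UMIs for macrophage-like, 13073.5 and 13547.5 for monocyte-like and 12847.5 and 15984 for NK-like cells. With the deeper tumour thinned to the same median of UMIs per cell the counts were 942 and 551, 124 and 187, and 88 and 160.

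The spatial codes were meant to mark cells from regions of YFP-bearing, RFP-bearing or mixed cancer cells, and the code of each region is not given in the sources used here, so classes were compared between codes and not between regions. Replicate 1 carried the codes ZC1, ZC2 and ZC5 and replicate 3 ZC1, ZC5 and ZC6. In both tumours monocyte-like cells were enriched among cells assigned to ZC1, which held relatively more ZC1 than their tumour's typical cell. Their share was 12.8% of ZC1 cells (131 of 1021, interval 10.8 to 15.04) against 1.45% of the other assigned cells (14 of 968, 0.793 to 2.41) in replicate 1. In replicate 3 it was 14.3% (131 of 919, 12.1 to 16.7) against 7.84% (130 of 1659, 6.59 to 9.24). In replicate 3 the ZC5 cells were close to ZC1, at 12.97% monocyte-like, and ZC6 cells lay at 3.85%, whereas in replicate 1 ZC2 and ZC5 cells lay at 0.875% and 1.76%. Macrophage-like cells made up 19.6% of ZC1, 34.7% of ZC2 and 55.8% of ZC5 cells in replicate 1, and 47.9% of ZC1, 44.3% of ZC5 and 60.1% of ZC6 cells in replicate 3. T-like cells made up 14.0%, 14.3% and 5.76% in replicate 1 and 10.4%, 13.1% and 11.6% in replicate 3, NK-like cells 4.70%, 2.62% and 0.48% and then 5.98%, 5.10% and 3.21%, and neutrophil-like cells 15.8%, 16.9% and 3.04% and then 2.07%, 0.138% and 0.535%.

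Most cells were not assigned to a code: 2643 of 4632 in replicate 1 and 3793 of 6371 in replicate 3 at the wider filter. Within 0.1 of the limit lay 767 and 1055 cells, so the assigned groups are ranges of a continuous ratio. Each cell held a mixture of codes, with a median of 516 and 281 code UMIs per cell. By the rule fixed before the data were examined, that 1 code takes at least 0.7 of a cell's code UMIs, 138 ZC1, 0 ZC2 and 6 ZC5 cells would have been assigned in replicate 1. In replicate 3 these would have been 22 ZC1, 23 ZC5 and 2381 ZC6 cells.

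**Figure D3:**
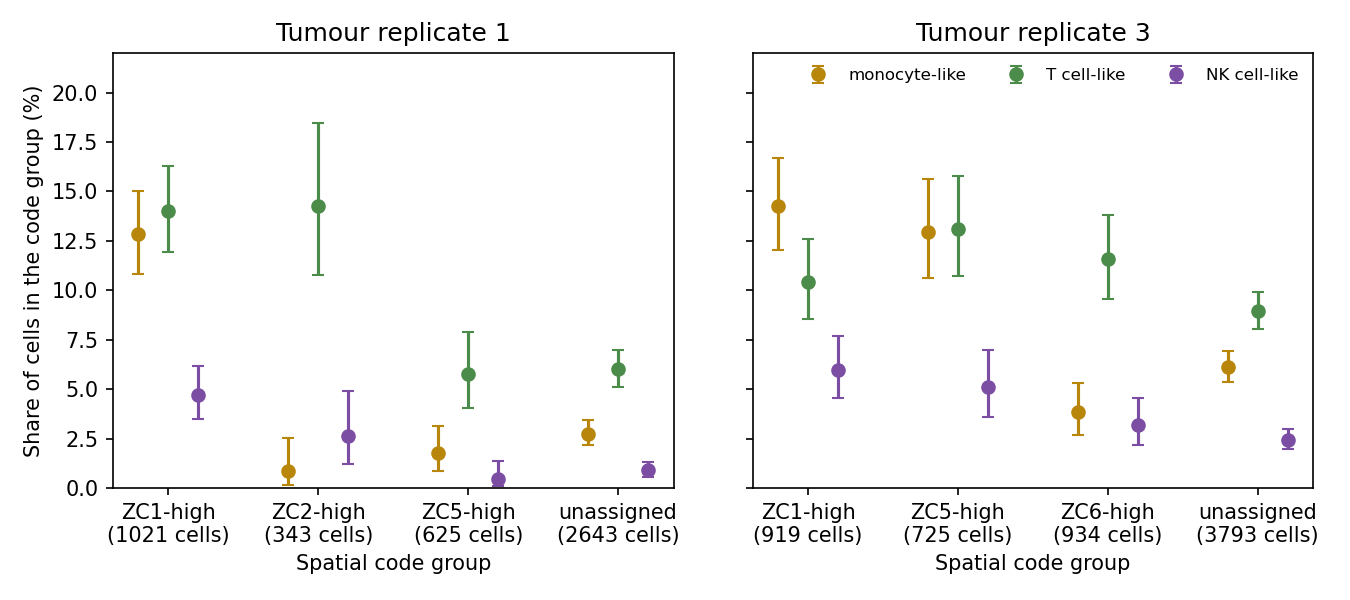
Share of cells (%, vertical axis) that were monocyte-like, T cell-like or NK cell-like in each spatial code group (horizontal axis, with cell numbers), 1 panel per tumour; points are shares and bars exact 95% intervals that cover counting error only. Monocyte-like cells reach 12.8% of ZC1 cells in replicate 1, and 14.3% of ZC1 and 12.97% of ZC5 cells in replicate 3. Code groups are relative to the tumour's typical cell.

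The reporters of the cancer cell lines reached their highest level in the small fibroblast-like class, which held 64 of the 134 RFP UMIs in called cells of replicate 1. YFP stood at 149 CPM (interval 130 to 170) in replicate 1 and 30.0 (23.2 to 38.1) in replicate 3, and RFP at 44.3 (34.1 to 56.6) and 27.7 (21.2 to 35.6). In macrophage-like cells YFP stood at 1.04 and 0.160 and RFP at 0.995 and 0.194, and barcodes with 1 to 20 UMIs, which hold mostly free RNA, had 3.79 and 1.41 for YFP and 2.37 and 0.353 for RFP. Of the 28 fibroblast-like cells of replicate 1, 6 had YFP UMIs alone, 9 RFP alone, 11 both and 2 neither, and of the 37 in replicate 3 these were 0, 22, 5 and 10. The class expressed the collagen gene Col1a1 at 1716 and 1935 CPM against 9.19 and 4.12 in macrophage-like cells, and Ptprc, which encodes CD45, at 28.4 and 3.63 against 344 and 267. Keratin transcripts of epithelial cells were uneven: Krt18 stood at 35.3 and 443 CPM and was seen in 5 of 28 and 13 of 37 cells. Krt5 had 0 UMIs, which allows up to 2.55 and 1.68 CPM (upper ends of the exact intervals), and the Krt8 level of replicate 3 came from 178 UMIs of 1 cell.

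**Figure D4:**
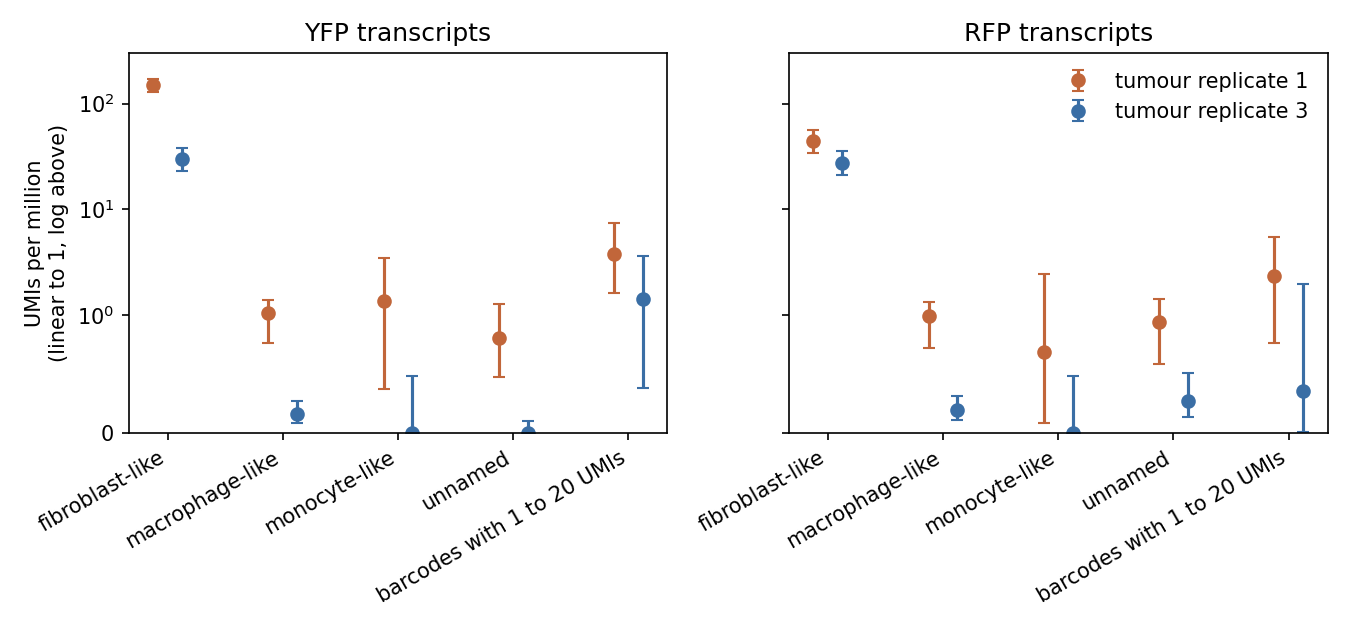
CPM (vertical axis, linear up to 1 and logarithmic above) of YFP and RFP, 1 panel each, in fibroblast-like, macrophage-like, monocyte-like and unnamed cells and in barcodes with 1 to 20 UMIs (horizontal axis), for each tumour; bars are exact Poisson 95% intervals. The fibroblast-like class stands highest, with YFP at 149 and 30.0 and RFP at 44.3 and 27.7 in replicates 1 and 3.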

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

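The test of free RNA as the source of the reporters and the rule that assigns codes to cells were chosen after the values were seen, and the other tests given here were set before. No biological explanation was tested, because the design holds 1 group.

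Signals outside the comparisons of classes drew attention because no control sample exists for them and they lie above the 3 counts that a count of 0 allows. Called cells held 283 YFP and 134 RFP UMIs in replicate 1, and 80 and 89 in replicate 3. Spatial code UMIs in called cells at the wider filter came to 3876851 in replicate 1 and 3178745 in replicate 3.

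YFP and RFP in the fibroblast-like class could come from free RNA or from cancer cells caught with leukocytes. In replicates 1 and 3 the reporters together were 31.4 and 32.7 times their level in barcodes with 1 to 20 UMIs. The lower bounds, 16.3 and 11.7, argue against free RNA. Leukocytes would bring Ptprc, which stood at 8.25% and 1.36% of the macrophage-like level. The interval of replicate 1 reached 11.4%, past the limit of 10 set for exclusion. But 10 of 28 and 6 of 37 cells held Ptprc, against 2196 of 2225 and 3072 of 3099 macrophage-like cells. That argues against joint capture for most of the class. With high Col1a1 and the keratin Krt14 at 0 and 4.997 CPM, the class was not named as cancer cells. How such cells passed the CD45 sort was not tested.

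The excess of monocyte-like cells among ZC1 cells could come from chance assignment where a cell holds few code UMIs, or from code uptake that differs by cell type. Among cells above the median of code UMIs the excess was 7.37 times in replicate 1 (3.11 to 20.4) and 2.60 times in replicate 3 (1.67 to 4.02), and the lower bound under 2 keeps the first of these open. For uptake, 90.8% of monocyte-like cells in replicate 1 and 69.8% in replicate 3 had a ZC1 log ratio above the macrophage-like median. That lies between the limits of 50 and 90 set beforehand. A high value could come from uptake by cell type or from position in the tumour, so this test cannot tell them apart. No source used here ties a code to a region.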

How the results depend on the processing

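Alternatives added after the data were seen were the wider filter for neutrophil-like and conventional DC-like cells, the filter of 500 UMIs and 300 genes for the same, the removal of the dividing lymphocyte cluster, and other rules for the codes. The cause of a change was not tested unless stated. Depth is low in lymphocytes, with median totals of 7220 and 12009 UMIs for CD8 T-like and 8305.5 and 14127 for regulatory T-like cells, and in neutrophil-like clusters, at 0.152 and 0.130 of their samples' medians at the wider filter.

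Without the replicate block macrophage-like against monocyte-like cells gave 8 genes higher and 1 lower, CD8 T-like against regulatory T-like cells 2 and 1, NK-like against CD8 T-like cells 0 and 0 in edgeR (359 and 194 at an unadjusted p under 0.05), T-like against mononuclear phagocyte-like cells 439 and 1058, and conventional DC-like against macrophage-like cells 207 and 168. Of the called genes 9 of 371, 3 of 106, 0 of 25, 1497 of 2620 and 375 of 863 were called there in the same direction, and 2368 of 2897 for neutrophil-like cells. For Cxcl9 in conventional DC-like against macrophage-like cells the sign turned without the block (-0.036).

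Each tumour alone gave shares of 58.0% to 60.2% for macrophage-like, 5.74% to 9.10% for monocyte-like, 2.65% to 3.33% for T-like and 2.73% to 3.14% for NK-like cells. Gene counts have no value there, since 1 tumour leaves no residual degrees of freedom.

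Cell settings moved the shares. Called cells of replicate 1 fell to 2178 at a mitochondrial limit of 5%. The macrophage-like share was 48.5% at the filter of 1000 UMIs and 500 genes, 45.5% at 500 UMIs and 300 genes, 56.1% and 61.0% at mitochondrial limits of 5% and 20%, 54.6% with doublets kept, 55.7% and 56.6% at resolutions 0.5 and 2, and 63.0% with scaling over both tumours. The monocyte-like share was 1.92% at 500 UMIs and 300 genes, 10.7% and 4.10% at the mitochondrial limits, 11.9% and 4.05% at the resolutions (5.49% and 2.60% in replicates 1 and 3 at resolution 2, the reverse order), and 4.55% with joint scaling. The T-like share was 9.19% and 9.10% at the wider filters, where shallow lymphocytes enter by construction and clusters were named anew. It was 2.08% at a limit of 20%, 1.89% with doublets kept, and 2.10% and 2.29% at the resolutions. The CD8 T-like share was 0.696% with doublets kept, 0.932% and 1.25% at the resolutions and 0.817% with split counts. It was 1.32% and 0.997% at the mitochondrial limits, 1.37% with joint scaling, and 2.18% and 2.15% at the wider filters. The NK-like share was 2.59% and 2.51% at the wider filters, 2.08% at a limit of 5%, 1.85% at resolution 2 and 2.59% with joint scaling.

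For macrophage-like against monocyte-like cells the count of lower genes was 238 with the Wald test and 62 with split counts. Higher and lower genes were 505 and 241 with no filter on low counts, where more genes were tested, 67 and 9 with free RNA subtracted, and 467 and 270 at 1000 UMIs and 500 genes. Of the 371 genes, 190 were called the same way with split counts, 76 with free RNA subtracted and 229 to 364 under the other settings that keep the block, with 0 changing sign. Signs turned for Cxcl9 at resolution 2 (2.13) and with split counts (1.35), for Cxcl10 with doublets kept (0.016), at resolutions 0.5 (0.51) and 2 (0.57) and with split counts (0.54), and for Arg1 with split counts (0.12).

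For CD8 T-like against regulatory T-like cells the count of lower genes was 88 with the Wald test. Higher and lower were 131 and 124 with no filter, 30 and 9 with free RNA subtracted, 256 and 102 at the wider filter, 9 and 2 at a mitochondrial limit of 5%, 10 and 10 at resolution 0.5, 9 and 7 at resolution 2, and 8 and 0 with split counts (227 and 345 at an unadjusted p under 0.05 in edgeR). Of the 106 genes 105 kept their call without the dividing cluster, which neither class contains, 39 with free RNA subtracted, 37 at the wider filter, 6 at a limit of 5%, 13 and 15 at the resolutions and 5 with split counts. Ccna2, Mki67 and Top2a turned to 6.07, 3.71 and 3.69 at the wider filter, to 11.60, 2.78 and 3.03 at a limit of 5%, and to 1.33, 1.24 and 1.66 at resolution 2. Cxcr6 turned at the wider filter (-0.038).

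For NK-like against CD8 T-like cells higher and lower were 38 and 29 with the Wald test, 115 and 52 with no filter, 0 and 0 in edgeR with free RNA subtracted (473 and 306 unadjusted) and 79 and 109 at the wider filter. Lower genes numbered 17 at a limit of 5%, 18 at resolution 0.5 and 27 at resolution 2, and higher genes 9 with split counts. Of the 25 genes 21 kept their call without the dividing cluster and 3 changed sign without passing: Ccna2, Cdk1 and Top2a turned to -1.65, -0.98 and -0.31, and Mki67 fell to 0.54, which ties these calls to its cells. Ccna2, Mki67, Cdk1 and Top2a turned to -4.91, -3.85, -3.70 and -3.70 at the wider filter and to -4.21, -3.16, -3.53 and -3.40 at resolution 2. Gzmb turned at a limit of 5% (-0.00482) and with split counts (-0.77).

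For T-like against mononuclear phagocyte-like cells split counts gave 560 higher and 961 lower. Of the 2620 genes 2147 were tested there, with 1306 called the same way and 2 changing sign. Birc5, Ccnb2 and Cdk1 turned at resolution 2 (0.82, 0.64 and 0.81). Cd274, which had not passed, turned with DESeq2's size factors (0.0025), at the wider filter (0.070), with doublets kept (0.14), at resolution 0.5 (0.23) and with split counts (0.27). At 500 UMIs and 300 genes neutrophil-like against monocyte-like cells gave 594 higher and 1085 lower. Of the 2897 genes 2753 were tested there, with 1472 called the same way and 27 changing sign. Cxcl16 (0.93), Psmb8 (0.041), Tubb5 (0.044), Cxcl10 (1.06) and Spp1 (1.05) turned. Cxcl10 also turned with the Wald test (0.0035). For conventional DC-like against macrophage-like cells lower genes numbered 688 with no filter, higher and lower 294 and 236 with free RNA subtracted, and higher genes 280 at resolution 2, where Cxcr6 turned (-0.12).

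For named genes 161, 143, 868, 390, 363 and 476 values under the alternatives counted as the same, in the order CD8 T-like, NK-like, T-like, conventional DC-like, macrophage-like and neutrophil-like comparisons. They kept their direction and their side of the threshold or, for single tumours, which have no threshold, lay within 1 SE of the joint estimate. Single tumours gave 11, 12, 54, 31, 24 and 20 of them without replicate 1, and 4, 10, 25, 18, 21 and 22 without replicate 3. Another 73, 46, 88, 65, 81 and 26 kept their direction and lost the call, and 2, 6, 1, 1, 10 and 2 gained it. Single tumours gave 27, 12, 85, 69, 31 and 114 values farther than 1 SE from the joint estimate. The monocyte-like excess among ZC1 cells was 7.77 and 1.54 times with a lead of 0.25, 4.98 and 2.25 with a lead of 1, and 8.59 and 1.91 with at least 100 code UMIs. Not run, or with no value because a class was missing or too small, were doublets kept for CD8 T-like and NK-like comparisons, neutrophil-like cells under a limit of 5%, doublets kept, other resolutions and split counts, conventional DC-like cells with doublets kept, at resolution 0.5 and with split counts, a code share of 0.5 for regions, and activated DC-like cells.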

Other observations

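The test of free RNA and that of dissociation stress given here were set before their results were seen, while the clusters and genes named in the first paragraphs were picked after. At the wider filter the T-like cells included CD4 helper T-like cells, at 1.58% of replicate 1 (73 cells) and 2.31% of replicate 3 (147 cells), and gamma delta T-like cells (3 and 15 cells). The cDC2-like class held 1.86% and 1.71% (86 and 109 cells), and activated DC-like cells, which bear the lymph node homing receptor Ccr7, numbered 16 and 17. A macrophage-like cluster of 69 and 129 cells was led by the interferon-induced genes Phf11b, Slfn5, Rtp4 and Oasl1, and no list was tested in it.

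Further lists differed between the tumours, with no test. In monocyte-like cells 6 of 13 MHC class I genes were at least 2-fold higher in replicate 3, and 4 of 12 myeloid-attracting chemokines were higher in replicate 1 and 1 in replicate 3. In macrophage-like cells 5 of 13 myeloid-attracting chemokines and 3 of 9 chemokine receptors were higher in replicate 1, and 0 in replicate 3. Ms4a4a was 11.7-fold higher in monocyte-like cells of replicate 1. NK-like cells of replicate 3 had more of 9 of 19 cell cycle genes and 3 of 12 cytotoxicity genes, with 0 and 1 higher in replicate 1. Ccl4, a chemokine of activated lymphocytes, was 25.7-fold higher in NK-like cells of replicate 3 (4 against 165 UMIs). The dividing lymphocyte cluster, which held 12 and 31 of the NK-like cells, was not left out here. NK-like cells of replicate 1 held 132 S100a8 UMIs against 0 (at least 70.7-fold higher) and 96 of the globin gene Hba-a1 against 0 (at least 51.4-fold higher), genes of neutrophils and red cells.

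The genes that differ between the tumours in macrophage-like cells may partly come from free RNA, or from stress during tissue dissociation. Over the 1520 genes at least 2-fold apart, the median level in NK-like cells was 45.1% of that in macrophage-like cells of the same tumour, between the limits of 25 and 50 set for exclusion and for a match, so free RNA and expression cannot be told apart by this value. Dissociation stress as a common source is argued against, since the 14 genes of that list had a median absolute log2 ratio of 0.19 between the tumours, below the limit of 1 set beforehand, although the most different member reached 2.18. The sex-linked transcripts show that the tumours also differ by the sex of the cells, and sex, animal and library cannot be separated with 1 sample each. No biological explanation was tested.

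Col1a1 was at 531 CPM in barcodes with 1 to 20 UMIs in replicate 3 and at 27.5 in replicate 1, so free RNA of the tumours differed in collagen. The median share of a cell's code UMIs that ZC6 took in replicate 3 was 66.5%, against 7.41% for ZC1 and 24.4% for ZC5, while in replicate 1 ZC1, ZC2 and ZC5 took 34.2%, 24% and 38.3%. Plasmacytoid DC-like cells made up 4.93% of ZC6 cells in replicate 3, against 2.61% of ZC1 and 2.07% of ZC5 cells, and CD8 T-like cells 2.89%, 2.39% and 5.52%. Of unassigned cells 2.76% in replicate 1 and 6.12% in replicate 3 were monocyte-like.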
